A study of Arabidopsis thaliana with 24 samples.

How the data were processed

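The series holds polyA RNA sequencing of detached Arabidopsis first-pair rosette leaves cultured on B5 medium without added hormone. Wild-type Col-0 leaves were sampled at time 0 and 10 min, 30 min, 1 h, 2 h, 4 h, 8 h and 12 h after culture began. Leaves of coi1-2, a mutant of the jasmonate receptor gene COI1, and of sdg8-2, which carries an insertion in the histone methyltransferase gene SDG8, were sampled at time 0 and 2 h. How much receptor function coi1-2 retains was not measured here. Each of the 12 groups has 2 libraries, described by the series as biological duplicates, which makes 24 libraries. Groups and replicate numbers were taken from the sample titles and characteristics.

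Trimmomatic, STAR 2.5.4b, RSEM 1.2.31 and the genome build TAIR10 were used per the submitters' processing notes, which give no parameters and no annotation. The authors deposited an RSEM gene file for each library, with 37686 genes. The deposited columns used here were the expected count (estimated reads or fragments per gene, not normalized), the TPM (transcript abundance scaled to the same total within each library) and the effective length (another unit, in bases per gene). Expected counts were rounded to whole numbers before fitting. Gene names and positions came from a TAIR10.1 annotation, in which 37390 of the identifiers were found and 296 were not. RSEM splits reads that align to more than 1 gene, so 5211 genes had a count that was not whole in at least 1 library. The level of a gene that shares reads in most libraries is uncertain, and this is stated where such a gene is named.

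Differential expression was tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): TMM normalization, filterByExpr by group, and the quasi-likelihood test with robust dispersion on 1 model with 12 group means and 12 residual degrees of freedom. Adjusted p is the Benjamini-Hochberg value over the 21097 genes tested, and a gene was called at an adjusted p below 0.05. The other 16589 genes had too few counts. Errors beside log2 fold changes are approximate standard errors. Each is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. They are least certain for genes near 0 counts in a group, and every group mean rests on 2 libraries. The 17 comparisons were 7 Col-0 times against time 0, any change along the Col-0 course, each mutant against Col-0 at each time, 2 h against time 0 within each mutant, the response of each mutant minus that of Col-0, and the coi1-2 response minus the sdg8-2 response. A set of genes that rose during culture, the induced set, was taken from other Col-0 libraries. Its genes were higher in the mean of 1 h and 4 h than at 10 min, called, by at least 2-fold. No rise above time 0 was required, and no leaves left on the plant were sampled beside the course. Effects of detachment, culture and time of day therefore cannot be told apart. The response of the set was compared between genotypes. Genes whose response minus the Col-0 response was called lower in both mutants were counted, whichever way they moved in Col-0. Beside this count stand 20 simulations of unchanged mutants against the same Col-0 libraries.

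Library totals ran from 35.6 to 62.6 M (M for 1e6) expected counts in Col-0, 30.1 to 37.5 M in coi1-2 and 30.2 to 36.1 M in sdg8-2. The procedure was tested on simulated data with the spread of these libraries and 200 changed genes. For a comparison of 2 groups it called 29% of genes changed 2-fold and 86% of those changed 4-fold, with 9 false calls. For a difference of responses it called 5% and 63%, with 3 false calls, so changes under 4-fold are often missed there. The real groups had unequal spread. The chi-square per degree of freedom of counts between replicates ran from 12.2 in coi1-2 at time 0 to 508 in sdg8-2 at time 0. False calls under such unequal spread were not simulated.

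Gene lists with 308 genes in all were fixed: jasmonate biosynthesis, JAZ repressors, jasmonate catabolism, jasmonate response, AP2/ERF factors, early wound and touch response, tryptophan and indole biosynthesis, TAA and YUCCA auxin biosynthesis, auxin response, root founder and root primordium, ethylene, abscisic acid and dehydration, salicylic acid, heat shock, glucosinolates, anthocyanin and flavonoid, photosynthesis, sugar starvation, cytokinin response, cell cycle, circadian clock, root tissue markers, shoot meristem markers, stomatal lineage and guard cell markers, phloem markers, and reference genes. Of these genes, 286 were tested. The shoot meristem list had fewer than 4 members tested and was left out. Each of the others was tested with camera at the preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated from the residuals. Beside a list's count of called genes over all genes tested stands the count adjusted over the list alone.

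The groups, the comparisons, the lists, the first set of other settings below and the rule for naming genes were written before the data were examined. By that rule the text draws on COI1 and SDG8 in every library, and on 10 key genes (ERF109, ASA1, AOS, JAZ10, MYC2, VSP2, WOX11, LBD16, ZAT10 and YUC9). It also draws on the 4 highest and 4 lowest fold changes of each comparison (6 and 6 in the 2 h and genotype comparisons) among called nuclear genes with a mean TPM of at least 5 and separate replicates, and on up to 4 members of each list with the smallest adjusted p. Not every gene selected was named. Genes with counts near 0 in a compared group, and genes whose call rested on single libraries, were mostly left out after their values were seen. Of the 119 named changes between 2 groups that passed the test, 118 had both libraries of one group beyond both of the other (LHCB1.1 did not). All 20 named differences of responses that passed had the same sign in both replicate pairs taken by label. Such order was a condition for naming part of these genes, so these counts do not measure how well replicates matched.

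Other settings tried were RLE size factors in place of TMM, no filter, a filter of CPM of at least 1 in 4 libraries, the replicate number as a block, offsets from the effective length, organelle genes left out, only the libraries of the groups compared in the fit, limma on log2(TPM + 1), DESeq2 1.42.0, a fold threshold of 2, and leaving out each library in turn. The limma setting took TPM as deposited, without TMM factors, so it differed from the reported test in scaling as well as in model. For lists the other settings were an estimated correlation, fry, RLE and the block. After the data were seen, 3 more were added: leaving out both sdg8-2 replicate 2 libraries, summing overlapping genes that share reads, and a separate replicate block in each genotype. The library numbers in the labels place all mutant libraries in another series than most Col-0 libraries, with 65 and 66 used in both. A difference between these series cannot be told apart from genotype when a mutant is compared with Col-0 at 1 time, whereas a constant shift cancels in a difference of responses.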

Results

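COI1, the receptor gene for jasmonate, was transcribed in every library of all 3 genotypes, whereas SDG8, a histone methyltransferase gene, was low in sdg8-2. COI1 (chromosome 2, 16672493 to 16675864) measured 7.40 to 23.14 TPM in the 16 Col-0 libraries, 14 and 15.47 TPM in coi1-2 at time 0, and 12.25 and 13.36 TPM at 2 h. In sdg8-2 COI1 stood at 15.34 and 14.59 TPM at time 0 and 11.65 and 8.07 TPM at 2 h. SDG8 (chromosome 1, 29039922 to 29049454) measured 5.31 to 11.57 TPM in Col-0, 7.67 and 8.95 TPM in coi1-2 at time 0, and 4.85 and 5.13 TPM at 2 h. In sdg8-2 SDG8 measured 2.55 and 2.86 TPM at time 0 and 0.58 and 0.29 TPM at 2 h. Reads of SDG8 were shared with other genes in all 24 libraries, so its level is uncertain.

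Within 10 min of detachment, genes of calcium, wound and stress signalling rose in Col-0. The BYPASS family gene BPS3 had a log2 fold change of 8.14 ± 0.79 (adjusted p 4.5e-05), the stress-signalling factor gene MYB15 7.86 ± 0.87 (0.00013), the calmodulin-like gene CML37 5.39 ± 0.75 (0.00084) and the zinc-finger repressor gene ZAT12 3.95 ± 0.51 (0.00044). ERF109 (chromosome 4, 16451876 to 16453260), an AP2/ERF factor gene of wound and redox signalling, rose by 6.38 ± 0.88 (0.00082), from 5.65 and 0.97 TPM to 343.36 and 172.92 TPM, with reads shared with another gene in 23 libraries. The zinc-finger gene ZAT10 rose by 3.14 ± 0.62 (0.011) and the jasmonate repressor gene JAZ1 by 2.26 ± 0.35 (0.0018). The jasmonate biosynthesis gene AOS measured 1.56 ± 0.43 (0.081), at 1250.29 and 343.90 TPM against 321.23 and 256.03 TPM. Among the early wound and touch genes the median was 2.47, with 12 of 21 called higher and 20 adjusted over the list alone (camera adjusted p 4.6e-38, and 0.00574 with an estimated correlation). AP2/ERF factors had 9 of 25 genes higher, 11 adjusted over the list alone (median 1.90, camera 2.92e-13, and 0.00873 with an estimated correlation). Jasmonate biosynthesis followed with 3 of 13 genes higher, 7 adjusted over the list alone (median 1.56, camera 5.91e-07; adjusted p = 0.363 with an estimated correlation). So did JAZ repressors, with 3 of 13 higher and 3 adjusted over the list alone (median 1.02, camera 4.81e-05; adjusted p = 0.365 with an estimated correlation). In all, 534 genes passed edgeR's quasi-likelihood test, 509 higher and 25 lower, 475 of them by at least 2-fold. The count was 289 when only the compared libraries were fitted and 884 with DESeq2. It was 219 without 10 min replicate 1, and 300 and 119 without time 0 replicates 1 and 2. Fitting only the compared libraries ended the calls of ERF109 (6.36), MYB15 (7.84) and JAZ1 (2.24). That of JAZ1 also ended without time 0 replicate 2 (2.1), and that of ZAT10 without 10 min replicate 1 (2.68) or time 0 replicate 1 (3.0) or 2 (3.25). AOS passed with DESeq2 (1.55) and without 10 min replicate 2 (2.18), and was down to 0.336 without 10 min replicate 1.

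By 30 min the genes that make, restrain and break down jasmonate had risen together. The repressor gene JAZ8 rose by 6.89 ± 0.71 (adjusted p 1.6e-05), JAZ10 by 4.72 ± 0.70 (0.00031), the hormone-oxidizing enzyme gene CYP94C1 by 6.81 ± 0.74 (2.2e-05), the biosynthesis gene OPR3 by 3.29 ± 0.51 (0.00038) and AOS (chromosome 5, 17097564 to 17099595) by 2.63 ± 0.45 (0.00077). Tryptophan synthesis genes also rose, ASA1, which encodes the first enzyme of the route (chromosome 5, 1719533 to 1722933), by 1.71 ± 0.33 (0.0019) and IGPS by 1.81 ± 0.23 (8.4e-05). The defence factor gene WRKY18 rose by 4.90 ± 0.56 (3.5e-05), and ERF109 was still higher by 5.95 ± 0.86 (0.00025), at 59.53 and 293.64 TPM in the replicates. Called higher were 11 of 13 JAZ repressors, 11 adjusted over the list alone (median 2.66, camera adjusted p 5.18e-09; adjusted p = 0.25 with an estimated correlation). Jasmonate biosynthesis had 11 of 13 higher, 11 adjusted over the list alone (2.63, 1e-08; adjusted p = 0.261 with an estimated correlation), and catabolism 9 of 10, 9 adjusted over the list alone (5.08, 1.08e-07; adjusted p = 0.25 with an estimated correlation). Also higher were 10 of 13 tryptophan genes, 11 adjusted over the list alone (1.41, 5.81e-06; adjusted p = 0.298 with an estimated correlation). The early wound list had 13 of 21 higher, 15 adjusted over the list alone (2.88, 4.14e-09; adjusted p = 0.25 with an estimated correlation). ASA1 and 3 more of the 13 tryptophan genes (ASB1, PAI1 and PAI2) shared reads with other genes, so their levels are uncertain. In all, 4594 genes passed the edgeR test, 2900 higher and 1694 lower, 2955 of them by at least 2-fold, and the higher ones included 453 of the 509 from 10 min. With limma on TPM most calls went the other way, 1706 higher and 2416 lower. The count was 821 when only the compared libraries were fitted, which also ended the call of ERF109 (5.93), and 2721, 2813 and 2388 without 30 min replicate 1 and time 0 replicates 1 and 2.

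At 1 h AOS transcript was at its highest mean TPM of the course, and genes of the tryptophan route rose. AOS rose by 3.89 ± 0.47 (adjusted p 1.8e-05), from 321.23 and 256.03 TPM to 3989.34 and 3720.94 TPM, and the catabolism gene CYP94B3 by 8.49 ± 1.29 (0.00012). JAZ10 was higher by 4.76 ± 0.71 (0.0001) and JAZ1 by 2.97 ± 0.36 (1.8e-05). In the tryptophan route, TSA1, the alpha subunit gene of tryptophan synthase, rose by 2.96 ± 0.23 (5.2e-07), IGPS by 3.3 ± 0.25 (4e-07) and ASA1 by 2.30 ± 0.34 (9.1e-05). The sugar-starvation factor gene BZIP1 fell by 3.43 ± 0.51 (0.0001) and the cyclin gene CYCD3;1 fell by 1.34 ± 0.20 (0.0001). The chaperone gene HSP90.1 rose by 6.36 ± 1.46 (0.0029). ERF109 was down to 2.75 ± 0.76 (0.0092) above time 0. Of 13 jasmonate biosynthesis genes 12 were higher, 12 adjusted over the list alone (median 3.53, camera adjusted p 2.82e-07). Of 10 catabolism genes 9 were, 9 adjusted over the list alone (6.01, 1.88e-05), and of 13 tryptophan genes 11, 11 adjusted over the list alone (2.30, 1.13e-08). Each had adjusted p = 0.491 with an estimated correlation. Cell cycle genes had 6 of 11 lower, 6 adjusted over the list alone (-0.95, 0.0229; adjusted p = 0.521 with an estimated correlation). With 8357 genes called by edgeR, 4628 higher and 3729 lower (5386 by at least 2-fold), this time had the most calls of the Col-0 course. With limma on TPM it had 3337 higher and 4157 lower. Without 1 h replicate 1 the count was 5511, and the call of ERF109 ended without that library (2.19) or time 0 replicate 2 (1.97).

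Tryptophan synthesis genes rose together at 2 h. TSA1 rose by 3.96 ± 0.24 (adjusted p 2.2e-07), IGPS by 3.57 ± 0.25 (6.9e-07), PAT1, the gene of the enzyme after ASA1, by 2.42 ± 0.25 (1.8e-05), the synthase beta subunit gene TSB1 by 2.12 ± 0.20 (9.8e-06). ASA1 rose by 2.36 ± 0.34 (0.0003), from 32.82 and 27.81 TPM to 183.46 and 146.38 TPM. Of 13 tryptophan genes 12 were called higher, 12 adjusted over the list alone (median 2.44, camera adjusted p 3.08e-24, and 0.0318 with an estimated correlation). AOS was still higher by 2.68 ± 0.45 (0.00092), and the storage protein genes VSP1 and VSP2, which jasmonate induces, rose by 5.97 ± 1.00 (0.00093) and 4.29 ± 1.06 (0.011). JAZ10 measured 1.61 ± 0.62 (0.084). The anthocyanin regulator gene PAP1 rose by 5.33 ± 1.06 (0.0035) and the auxin synthesis gene YUC2 by 1.60 ± 0.44 (0.019). LBD16, a factor gene of root initiation, passed the test (0.0018) at 0.86 and 0.83 TPM against 0.04 and 0.02 TPM. YUC9, another auxin synthesis gene, stood at 0.13 and 0.20 TPM against 0.03 and 0.02 TPM (0.12), and the root founder gene WOX11 at 0 in both. ERF109 was back at 0.44 and 0.83 TPM. Genes that fell were the cell wall gene EXPA8 (-6.37 ± 1.12, 0.0013), the gibberellin-regulated gene GASA6 (-6.19 ± 0.80, 0.00013), the cytokinin response gene ARR5 (-2.88 ± 0.62, 0.0049) and ZAT10 (-1.97 ± 0.60, 0.032). In all, 4101 genes passed the edgeR test, 2405 higher and 1696 lower, 2428 of them by at least 2-fold. The count was 1688 and 2375 without 2 h replicates 1 and 2, 1614 without time 0 replicate 2, and 6400 with both sdg8-2 replicate 2 libraries left out, where YUC9 passed. JAZ10 passed with DESeq2 (1.60) and without time 0 replicate 1 (2.77), and was down to 0.969 without time 0 replicate 2. Calls ended without 2 h replicate 1 for VSP2 (3.76), YUC2 (1.32), ARR5 (-2.47) and ZAT10 (-1.86). They ended without time 0 replicates 1 and 2 for VSP2 (4.23 and 4.36), YUC2 (1.64 and 1.55) and ZAT10 (-2.09 and -1.85), and for ZAT10 also without 2 h replicate 2 (-2.07) and with no filter (-1.97).

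The other lists at 2 h moved in both directions. Higher were 8 of 10 jasmonate catabolism genes, 9 adjusted over the list alone (median 4.50, or 3.29 with genes at 0 counts set to a floor of 3 counts per library; camera adjusted p 5.36e-06; adjusted p = 0.253 with an estimated correlation). Anthocyanin and flavonoid genes had 7 of 10 higher, 10 adjusted over the list alone (3.06, 0.00274; adjusted p = 0.253 with an estimated correlation). Jasmonate biosynthesis had 6 of 13 higher and 1 lower, 8 and 1 adjusted over the list alone (1.11, 0.00633; adjusted p = 0.598 with an estimated correlation). Root founder genes had 3 of 4 higher, 3 adjusted over the list alone (2.76, or 1.94 at the floor). The camera adjusted p of this list was 0.00633, and 0.148 with an estimated correlation. Only 4 of its 10 genes passed the count filter. A gene near 0 counts at time 0 can pass that filter through later groups where it is high, which may favour higher calls. Abscisic acid genes had 4 of 13 higher, 6 and 1 lower adjusted over the list alone (1.92, 0.013; adjusted p = 0.598 with an estimated correlation). Heat shock genes had 4 of 10 higher, 6 adjusted over the list alone (4.27, or 3.22 at the floor; 0.0119; adjusted p = 0.598 with an estimated correlation). Lower were 4 of 9 sugar starvation genes, 5 adjusted over the list alone (-2.13, 0.00633), and 3 of 8 cytokinin response genes, 4 adjusted over the list alone (-1.38, 0.0109), both with adjusted p = 0.404 with an estimated correlation. Cell cycle genes had 2 of 11 lower, 2 adjusted over the list alone (-0.59, 0.00969), and photosynthesis genes 0 of 18, 0 adjusted over the list alone (-0.85, 0.0139), both with adjusted p = 0.598 with an estimated correlation. Of the photosynthesis genes 3 were lower at an unadjusted p below 0.05 in edgeR and 3 by DESeq2. The call was 16 lower with both sdg8-2 replicate 2 libraries left out (-0.84, 3.18e-07), and with a replicate block in each genotype 13 (-0.84, 2.14e-06). AP2/ERF factors split into 6 higher and 10 lower of 25, 9 and 11 adjusted over the list alone, and early wound genes into 3 higher and 6 lower of 21, 3 and 7 adjusted over the list alone, and neither passed camera. Nor did the remaining lists: jasmonate response (6 of 13 higher, 1 lower), JAZ repressors (1 of 13 lower), TAA and YUCCA genes (1 of 9 higher), auxin response (1 of 13 higher), ethylene (2 of 10 higher, 2 lower), salicylic acid (1 of 9 higher, 3 lower), glucosinolates (1 of 10 higher, 1 lower), circadian clock (0 of 16 by edgeR, 0 at an unadjusted p below 0.05 and 0 by DESeq2), root tissue (1 of 6 higher), stomatal lineage (2 of 8 higher, 1 lower), phloem (1 of 6 lower) and reference genes (1 of 8 higher). Adjusted over the list alone, the counts of these differed for jasmonate response (7 higher, 2 lower), JAZ repressors (0) and glucosinolates (2 higher, 1 lower). The count of 0 clock genes does not show that none changed, since the fit takes 1 spread per gene from all libraries. Clock genes differed between the sdg8-2 replicates by a median absolute log2 of 4.33 at time 0 and 3.18 at 2 h. With both sdg8-2 replicate 2 libraries left out, 2 of 16 clock genes were called lower (median -0.08, camera adjusted p 0.656).

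**Figure D1:**
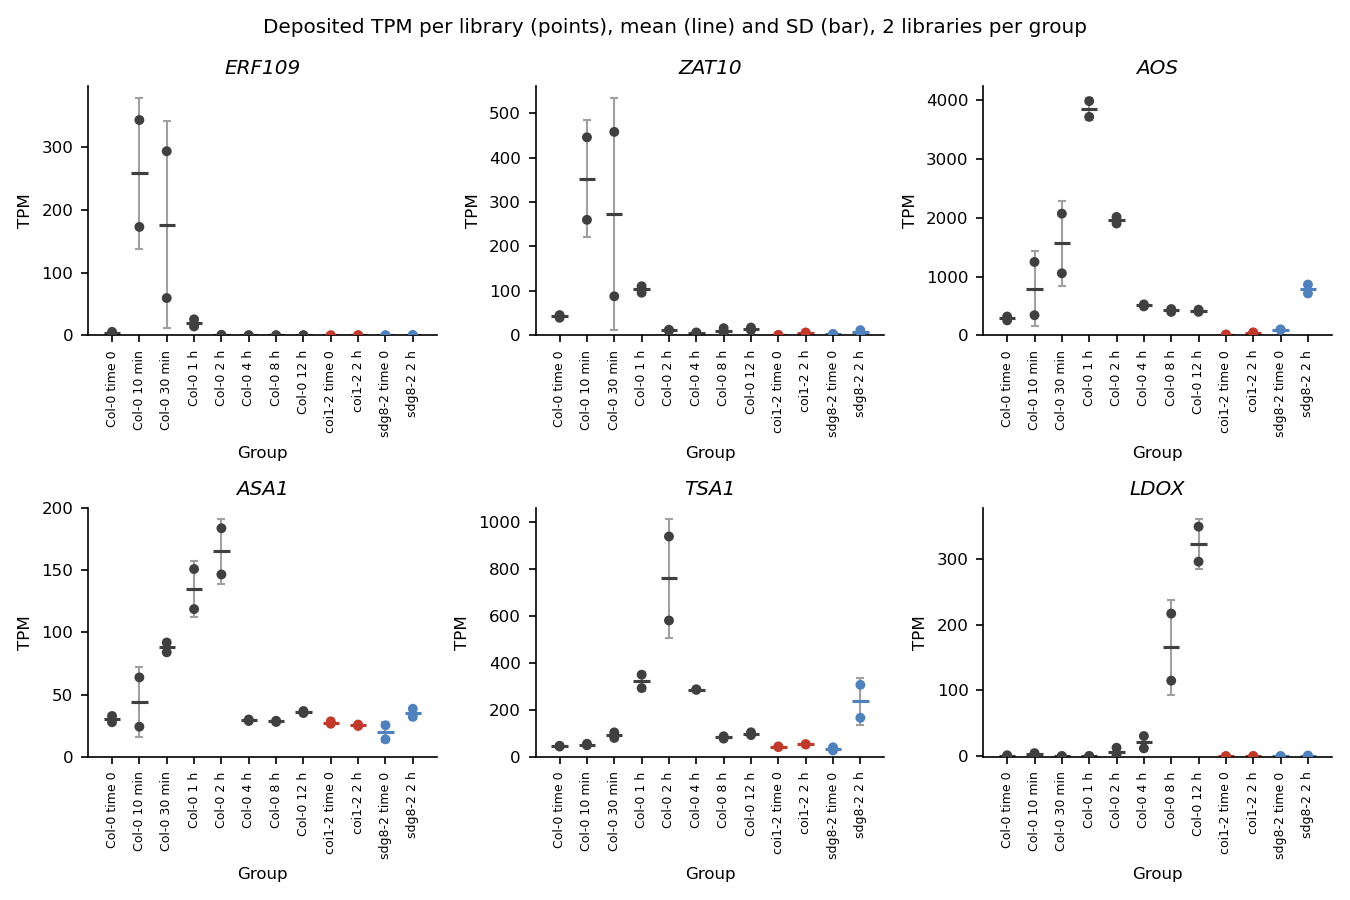
Deposited TPM of 6 genes (y axis) in each of the 12 groups (x axis), with 1 point per library, the mean as a line and the SD of 2 libraries as a bar. ERF109 and ZAT10 peaked at 10 to 30 min, AOS at 1 h with 3989.34 and 3720.94 TPM, ASA1 at 2 h with 183.46 and 146.38 TPM together with TSA1, and LDOX rose at 8 to 12 h.

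At 4 h pigment regulation and part of the tryptophan route were still raised, and division genes had fallen. ASA1 measured -0.21 ± 0.32 (adjusted p 0.74) and AOS 0.66 ± 0.42 (0.36), while TSA1 was still higher by 2.47 ± 0.23 (1.4e-05) and PAP1 by 6.46 ± 1.11 (0.003). Falls were called for the DNA replication gene MCM2 (-1.28 ± 0.27, 0.0078), the cytokinin oxidase gene CKX4 (-2.15 ± 0.44, 0.0071), GASA6 (-6.53 ± 0.82, 0.00024) and ZAT10 (-2.98 ± 0.63, 0.0085). LBD16 stood at 0.84 and 1.35 TPM (0.0028). The lists counted 7 of 10 anthocyanin genes higher, 10 adjusted over the list alone (median 4.05, camera adjusted p 1.37e-06; adjusted p = 0.0846 with an estimated correlation). Cell cycle genes had 5 of 11 lower, 9 adjusted over the list alone (-0.99, 1.37e-06; adjusted p = 0.116 with an estimated correlation). Cytokinin response genes had 5 of 8 lower, 5 adjusted over the list alone (-1.73, 1.25e-05; adjusted p = 0.1 with an estimated correlation). Sugar starvation genes had 5 of 9 lower, 7 adjusted over the list alone (-2.51, 1.02e-05; adjusted p = 0.116 with an estimated correlation). In all, 2043 genes passed the edgeR test, 1172 higher and 871 lower, 1420 of them by at least 2-fold, against 1842 higher and 550 lower with limma on TPM. The count was 3176 with DESeq2 and 3994 with both sdg8-2 replicate 2 libraries left out. It was 560 and 880 without 4 h replicates 1 and 2, and 462 without time 0 replicate 2. Calls ended without 4 h replicate 1 for CKX4 (-1.90) and ZAT10 (-2.82), without 4 h replicate 2 for MCM2 (-1.17) and ZAT10 (-3.15), and without time 0 replicate 2 for ZAT10 (-2.84).

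Pigment synthesis genes rose at 8 h, and cytokinin response genes fell. The anthocyanin enzyme genes DFR and LDOX rose by 8.95 ± 1.33 (adjusted p 0.0015) and 7.55 ± 1.16 (0.0012). The cytokinin response gene ARR4 (-2.88 ± 0.38, 0.0004) and GASA6 (-6.14 ± 0.80, 0.00036) fell. LBD16 stood at 1.31 and 1.24 TPM (0.0019). Of 10 anthocyanin genes 9 were higher, 10 adjusted over the list alone (median 5.99, camera adjusted p 1.51e-08, and 0.0299 with an estimated correlation). Of 8 cytokinin genes 6 were lower, 8 adjusted over the list alone (-2.52, 2.92e-08, and 0.0378 with an estimated correlation). Sugar starvation genes had 5 of 9 lower, 7 adjusted over the list alone (-3.11, 4.62e-05; adjusted p = 0.165 with an estimated correlation). In all, 2758 genes passed the edgeR test, 1383 higher and 1375 lower, 1594 of them by at least 2-fold. The balance was 1733 higher and 549 lower with limma on TPM, and 1358 and 850 with no filter. The count was 5110 with both sdg8-2 replicate 2 libraries left out, 625 and 785 without 8 h replicates 1 and 2, and 382 without time 0 replicate 2.

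At 12 h pigment genes were far above time 0 and reads of root founder genes were present. LDOX rose by 8.45 ± 1.2 (adjusted p 0.00047), DFR by 9.98 ± 1.38 (0.00066) and PAP1 by 7.39 ± 1.15 (0.0012). ASA1 measured 0.07 ± 0.32 (0.91). LBD16 stood at 1.77 and 1.58 TPM (0.00088), and WOX11 at 0.22 and 0.17 TPM after 0.07 and 0.14 TPM at 8 h and 0 in every earlier Col-0 library. Lower were ARR4 (-3.53 ± 0.40, 8.3e-05), the trehalose phosphate synthase gene TPS9, which sugar represses (-3.19 ± 0.54, 0.0016), EXPA8 (-7.48 ± 1.19, 0.0011) and GASA6 (-8.47 ± 0.90, 5.1e-05). Anthocyanin genes had 9 of 10 higher, 10 adjusted over the list alone (median 6.77, camera adjusted p 2.62e-09, and 0.019 with an estimated correlation). Cytokinin genes had 4 of 8 lower, 7 adjusted over the list alone (-2.80, 8.76e-08; adjusted p = 0.0502 with an estimated correlation). Sugar starvation genes had 7 of 9 lower, 8 adjusted over the list alone (-3.19, 2.22e-05; adjusted p = 0.135 with an estimated correlation). In all, 3344 genes passed the edgeR test, 1736 higher and 1608 lower, 2005 of them by at least 2-fold, against 2564 higher and 730 lower with limma on TPM. Over the whole course 11118 genes (52.7%) changed, 7000 of them by at least 2-fold at some time. The 12 h count was 5653 with both sdg8-2 replicate 2 libraries left out, 1080 and 1173 without 12 h replicates 1 and 2, and 651 without time 0 replicate 2.

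**Figure D2:**
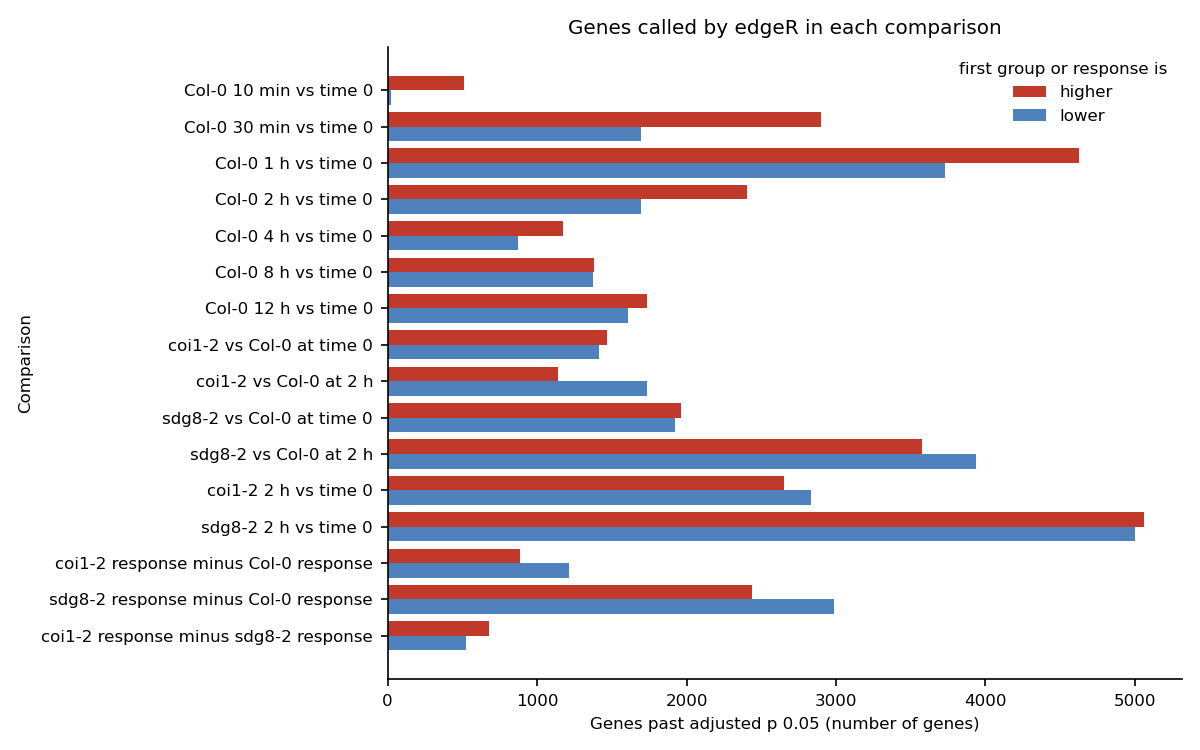
Number of genes past the edgeR test (x axis) that were higher or lower in each of 16 comparisons (y axis), with 2 libraries per group and no error bar, since each bar is a single count. The Col-0 course peaked at 1 h with 4628 higher and 3729 lower, and sdg8-2 at 2 h against time 0 had the longest bars with 5062 and 5000. All bars use 1 spread per gene from all libraries, though the sdg8-2 replicates stood far apart. With only the compared libraries fitted, fewer genes were called within sdg8-2 than within coi1-2, so bar lengths do not rank the responses of the genotypes.

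In coi1-2 leaves at time 0 the jasmonate, wound and glucosinolate genes were low before culture began. Against Col-0, AOS measured -4.48 ± 0.49 (adjusted p 0.00015), the biosynthesis gene LOX4 -6.95 ± 0.74 (0.00014), JAZ1 -5.41 ± 0.41 (1.3e-05), JAZ5 -7.07 ± 0.85 (0.00035) and ZAT10 -5.62 ± 0.74 (0.00065). The glucosinolate synthesis genes CYP79F1 and MAM1 measured -7.60 ± 0.67 (4.1e-05) and -3.98 ± 0.38 (6e-05). The inositol oxygenase gene MIOX2 measured 8.59 ± 1.26 (0.0013), ASA1 -0.15 ± 0.32 (0.79) and COI1 itself -0.03 ± 0.17 (0.93). Lower were 7 of 10 glucosinolate genes, 8 adjusted over the list alone (median -3.14, camera adjusted p 5.21e-18, and 0.0166 with an estimated correlation). Jasmonate biosynthesis had 10 of 13 lower, 11 adjusted over the list alone with 1 higher (-3.98, 5.86e-19; adjusted p = 0.0579 with an estimated correlation). JAZ repressors had 9 of 13 lower, 11 adjusted over the list alone (-3.65, 8.27e-14; adjusted p = 0.0599 with an estimated correlation). Early wound genes had 14 of 21 lower, 17 adjusted over the list alone (-2.57, or -2.43 at the floor, 1.06e-12; adjusted p = 0.0599 with an estimated correlation). AP2/ERF factors had 9 of 25 lower, 10 adjusted over the list alone (-2.33, or -2.16 at the floor, 3.3e-06; adjusted p = 0.0599 with an estimated correlation). In all, 2885 genes passed the edgeR test, 1471 higher and 1414 lower, 1674 of them by at least 2-fold. The count was 5652 when only the compared libraries were fitted and 5146 with both sdg8-2 replicate 2 libraries left out. Without single libraries it was 447 and 424 (coi1-2 replicates 1 and 2) and 640 and 1260 (Col-0 replicates 1 and 2). The library numbers place the mutants in another series than most Col-0 libraries, so differences from Col-0 at 1 time and a series effect cannot be told apart.

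At 2 h coi1-2 leaves held less transcript of jasmonate and tryptophan genes than Col-0 leaves. TSA1 measured -3.74 ± 0.24 (adjusted p 1.7e-06), IGPS -3.72 ± 0.25 (1.7e-06), ASA1 -2.61 ± 0.34 (0.00027), at 25.93 and 24.81 TPM. CYP79B2, whose enzyme turns tryptophan into indole compounds, measured -6.47 ± 0.51 (3.8e-06). AOS measured -5.26 ± 0.51 (1.8e-05), JAZ1 -4.11 ± 0.38 (1.4e-05), JAZ10 -2.96 ± 0.66 (0.01). The catabolism gene JOX2 measured -5.79 ± 0.72 (0.00017), and VSP1 and VSP2 -8.46 ± 1.12 (0.00029) and -8.54 ± 1.3 (0.00091). Glucosinolate genes were low as at time 0, BCAT4 at -7.70 ± 0.62 (4.1e-06) and MAM1 at -5.03 ± 0.40 (3.9e-06). ZAT10 measured -0.82 ± 0.59 (0.38) and COI1 -0.33 ± 0.17 (0.21). LBD16 stood at 0.37 and 0.44 TPM, and the jasmonate factor gene MYC2 had 0 counts in all 4 coi1-2 libraries, though it shares reads with an overlapping gene and its level is uncertain. Lower were 11 of 13 tryptophan genes, 11 adjusted over the list alone (median -3.0, camera adjusted p 2.87e-40, and 0.00394 with an estimated correlation). Jasmonate biosynthesis had 13 of 13 lower, 13 adjusted over the list alone (-3.28, 1.11e-20, and 0.0302). Also lower were 10 of 10 catabolism genes, 10 adjusted over the list alone (-6.12, or -5.43 at the floor, 2.11e-12, and 0.0394 with an estimated correlation). Glucosinolates had 7 of 10 lower and 1 higher, 7 and 1 adjusted over the list alone (-2.86, 5.4e-15, and 0.0178). Jasmonate response genes had 7 of 13 lower and 1 higher, 10 and 1 adjusted over the list alone (-3.09, or -0.97 at the floor, 6.36e-07, and 0.0437). JAZ repressors had 10 of 13 lower, 11 adjusted over the list alone (-2.74, 1.8e-11; adjusted p = 0.0637 with an estimated correlation). Early wound genes had 0 of 21 lower or higher, 0 adjusted over the list alone (-0.40, 0.604), with 1 higher and 3 lower at an unadjusted p below 0.05 in edgeR and 1 and 1 by DESeq2. In all, 2876 genes passed the edgeR test, 1138 higher and 1738 lower, 1419 of them by at least 2-fold. The count was 7823 when only the compared libraries were fitted, where COI1 (-0.33) and ZAT10 (-0.83) passed. It was 4916 with both sdg8-2 replicate 2 libraries left out. Without coi1-2 replicates 1 and 2 it was 512 and 846 and the call of JAZ10 ended (-3.01 and -2.89). Without Col-0 replicates 1 and 2 it was 911 and 1131, with JAZ10 at -2.63 and not called without the latter.

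In sdg8-2 leaves at time 0, SDG8 was lower by log2 -1.63 ± 0.24 (adjusted p 0.00074) and early wound genes were low as in coi1-2. JAZ1 measured -3.59 ± 0.38 (4.5e-05), LOX4 -4.59 ± 0.65 (0.00056), ZAT10 -3.69 ± 0.66 (0.0023). The immune regulator gene EDS1 measured -1.71 ± 0.29 (0.0018), CYP79F1 -2.02 ± 0.48 (0.012) and ASA1 -0.52 ± 0.32 (0.27). The lowest in this genotype included 3 genes with no symbol, AT4G19870 at -5.42 ± 0.30 (3.9e-08), AT5G56380 at -5.43 ± 0.43 (2.9e-06) and AT5G60030 at -5.30 ± 0.46 (7.6e-06). AT1G67105, also without a symbol, was higher by 9.55 ± 0.47 (9.5e-09). Early wound genes had 14 of 21 lower, 18 adjusted over the list alone (median -2.17, or -2.15 at the floor, camera adjusted p 7.93e-11; adjusted p = 0.444 with an estimated correlation). Jasmonate biosynthesis genes had 7 of 13 lower, 8 adjusted over the list alone (-1.57), and JAZ repressors 6 of 13, 8 adjusted over the list alone (-2.13), each at 5.06e-06 and adjusted p = 0.448 with an estimated correlation. Early wound genes had 9 lower with both sdg8-2 replicate 2 libraries left out (-2.19, 1.23e-08). Salicylic acid genes had 3 of 9 lower, 6 adjusted over the list alone (-1.71, 0.0014; adjusted p = 0.448 with an estimated correlation). In all, 3887 genes passed the edgeR test, 1964 higher and 1923 lower, 2082 of them by at least 2-fold. With limma on TPM 877 were higher and 2070 lower. The replicates stood far apart, and with both sdg8-2 replicate 2 libraries left out 3428 genes were called, 56.4% of the reported calls among them. When only the compared libraries were fitted 1 gene was called, AT1G67105. The others named missed the threshold there, with SDG8 at -1.65, JAZ1 at -3.61, LOX4 at -4.61, ZAT10 at -3.70, EDS1 at -1.73, CYP79F1 at -2.04, AT4G19870 at -5.43, AT5G56380 at -5.45 and AT5G60030 at -5.32. Without single libraries the count was 5916 and 2435 (sdg8-2 replicates 1 and 2) and 1335 and 1793 (Col-0 replicates 1 and 2). CYP79F1 was not called without Col-0 replicate 1 (-1.67).

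Tryptophan genes were lower in sdg8-2 than in Col-0 at 2 h. TSB1 measured -1.97 ± 0.20 (adjusted p 2.1e-05), PAT1 -1.75 ± 0.24 (0.00014), TSA1 -1.34 ± 0.22 (0.00041) and ASA1 -1.80 ± 0.33 (0.00091), at 32.13 and 38.63 TPM. AOS measured -0.93 ± 0.42 (0.1), VSP2 0.07 ± 0.93 (0.96) and ZAT10 -0.11 ± 0.59 (0.9). LBD16 stood at 0.52 and 0.35 TPM. The salicylic acid receptor gene NPR1 measured -1.14 ± 0.17 (0.00027), the myrosinase gene TGG2 -1.31 ± 0.15 (5.9e-05) and SDG8 -4.10 ± 0.27 (3.1e-07). The retroelement SADHU3-2 measured 9.0 ± 0.79 (6.7e-06) and AT1G67105 10.19 ± 0.49 (1.5e-08). Tryptophan genes had 9 of 13 lower, 10 adjusted over the list alone (median -1.34, camera adjusted p 0.000158; adjusted p = 0.829 with an estimated correlation). Jasmonate biosynthesis had 3 of 13 lower, 3 adjusted over the list alone (-0.95, 0.0506), and jasmonate response 4 of 13, 4 adjusted over the list alone (-0.81, 0.197). Of 18 photosynthesis genes 9 were higher, 9 adjusted over the list alone (1.56, 0.186). With both sdg8-2 replicate 2 libraries left out, the tryptophan count was again 9 lower (-1.12) but photosynthesis had 3 lower. The jasmonate biosynthesis list then passed camera with 5 lower (-1.12, 0.017) and the response list with 4 (-1.37, 0.0292). With a replicate block in each genotype neither passed, while photosynthesis had 13 higher and passed (1.01, 1.75e-05). The antenna protein gene LHCB1.1, which shares reads in all 24 libraries, went from 6.82 ± 1.99 (0.015) to -0.088 with both sdg8-2 replicate 2 libraries left out. In all, 7514 genes passed the edgeR test, 3578 higher and 3936 lower, 3690 of them by at least 2-fold. With limma on TPM 1211 were higher and 6000 lower. The count was 2796 when only the compared libraries were fitted, and 4529, 4737 and 4572 without sdg8-2 replicate 2 and Col-0 replicates 1 and 2. The value of LHCB1.1 was -0.093 without sdg8-2 replicate 2. Its call ended without Col-0 replicates 1 (6.51) or 2 (7.16), with limma on TPM (3.5) and when only the compared libraries were fitted (6.84). The last setting also ended the call of TSA1 (-1.33), while AOS passed with limma on TPM (-1.32). VSP2 ran from -1.12 without sdg8-2 replicate 2 to 0.691 without replicate 1.

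Within coi1-2, part of the early wound genes rose over 2 h of culture, from a low start. Against Col-0 their median was -2.57 at time 0, and at 2 h 0 of 21 were called. In Col-0 this list moved in both directions over the same time, with ZAT10 going from 39.65 and 45.69 TPM to 10.6 and 12.71 TPM. ZAT10 rose by 2.83 ± 0.69 (adjusted p 0.0091), the jasmonate synthesis gene AOC2 by 3.63 ± 0.48 (0.00023), AOS by 1.90 ± 0.44 (0.0067), from 13.29 and 12.81 TPM to 44.60 and 51.43 TPM, and JOX2 by 3.13 ± 0.71 (0.0063). CYP79B2 (-2.80 ± 0.43, 0.0007) and the beta-xylosidase gene BXL1, which low sugar induces (-4.54 ± 1.01, 0.0055), fell. ASA1 measured -0.10 ± 0.32 (0.85). Of 21 early wound genes 9 were higher and 2 lower, 9 and 2 adjusted over the list alone (median 1.49, camera adjusted p 0.00022; adjusted p = 0.542 with an estimated correlation). Tryptophan genes had 2 of 13 higher and 3 lower, 2 and 3 adjusted over the list alone (0.21, 0.946). In all, 5482 genes passed the edgeR test, 2651 higher and 2831 lower, 2672 of them by at least 2-fold. The count was 11965 when only the compared libraries were fitted. It was 1735 and 2716 without 2 h replicates 1 and 2, and 2299 and 2076 without time 0 replicates 1 and 2. Calls ended without time 0 replicate 1 for ZAT10 (2.97) and JOX2 (3.13), without time 0 replicate 2 for ZAT10 (2.74), JOX2 (3.15) and AOS (1.86), and without 2 h replicates 1 and 2 for BXL1 (-4.49 and -4.55).

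Within sdg8-2, JAZ repressor and tryptophan genes rose in 2 h, as did the other jasmonate genes named here. AOS rose by 3.14 ± 0.46 (adjusted p 5.9e-05), JAZ1 by 2.12 ± 0.36 (0.00019), JOX2 by 4.22 ± 0.66 (0.00012), VSP1 by 5.84 ± 0.99 (0.00022) and VSP2 by 4.92 ± 1.09 (0.0018). IGPS rose by 3.32 ± 0.25 (6.2e-07), TSA1 by 2.93 ± 0.23 (8e-07) and ASA1 by 1.08 ± 0.33 (0.013). Tryptophan genes had 12 of 13 higher, 12 adjusted over the list alone (median 1.74, camera adjusted p 2.15e-06). JAZ repressors had 10 of 13 higher, 11 adjusted over the list alone (2.12, 0.00663), and early wound genes 10 of 21, 10 adjusted over the list alone (1.60, 0.00663). Each had adjusted p = 0.742 with an estimated correlation. With both replicate 2 libraries left out JAZ repressors had 6 higher (1.44, 0.0189), early wound genes 9 (2.099, 0.0123) and tryptophan genes 10 (1.67, 5.33e-05). Jasmonate biosynthesis then had 6 of 13 higher and 1 lower (1.55, 0.0178) and catabolism 6 of 10 higher (4.66, 0.0143). The jasmonate response list had 3 of 13 higher and 2 lower and did not pass camera (0.10, 0.536). In all, 10062 genes passed the edgeR test, 5062 higher and 5000 lower, 6413 of them by at least 2-fold. The count was 904 when only the compared libraries were fitted, where the calls of JAZ1 (2.11), ASA1 (1.07) and VSP2 (4.91) ended. With both replicate 2 libraries left out ASA1 (0.49) and VSP2 (3.24) were not called, nor was ASA1 without 2 h replicate 2 (0.73) or time 0 replicate 2 (0.88).

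The response of coi1-2 differed from that of Col-0 in opposite ways for the tryptophan and the early wound genes. The difference was -3.63 ± 0.31 for TSA1 (adjusted p 0.00013), -3.08 ± 0.33 for IGPS (0.00043), -5.87 ± 0.61 for CYP79B2 (0.00042), -4.14 ± 0.50 for CYP83B1, another indole enzyme gene (0.001). For ASA1 it was -2.46 ± 0.46 (0.0086). It was 4.80 ± 0.91 for ZAT10 (0.0089) and 3.99 ± 0.79 for the factor gene ERF1A (0.01), which had fallen by 3.95 ± 0.60 in Col-0 (0.0005). MIOX2 measured -7.64 ± 1.44 (0.0087) and AOS -0.78 ± 0.60 (0.43). Tryptophan genes had 10 of 13 with a lower response, 10 adjusted over the list alone (median -2.46, camera adjusted p 9.78e-22, and 0.0464 with an estimated correlation). Early wound genes had 5 of 21 with a higher response, 12 adjusted over the list alone (1.89, or 1.85 at the floor, 2.25e-07; adjusted p = 0.471 with an estimated correlation). Against Col-0 these 21 genes had a median of -2.57 at time 0 and 0 called at 2 h, so their higher response lay mostly in the start. A raised Col-0 level at time 0 and a genotype effect cannot be told apart there. AP2/ERF factors had 5 of 25 with a higher response, 5 with 1 lower adjusted over the list alone (1.52, or 1.09 at the floor, 0.00327; adjusted p = 0.471 with an estimated correlation). In all, 2097 genes passed the edgeR test, 886 higher and 1211 lower, 1508 of them by at least 2-fold. The count was 6761 when only the compared libraries were fitted, where AOS passed (-0.78). It was 3555 with DESeq2, 3243 with a replicate block in each genotype and 4333 with both sdg8-2 replicate 2 libraries left out. The count was 311 and 567 without coi1-2 2 h replicates 1 and 2, 673 and 305 without coi1-2 time 0 replicates 1 and 2, where the latter ended the calls of ZAT10 (4.71) and ERF1A (3.88). It was 522 and 641 without Col-0 2 h replicates 1 and 2, and 1012 and 607 without Col-0 time 0 replicates 1 and 2.

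The sdg8-2 response minus that of Col-0 was lower for part of the tryptophan route and higher for early wound genes, which had started low. The difference from Col-0 was -1.55 ± 0.27 for TSB1 (adjusted p 0.0011), -1.03 ± 0.30 for TSA1 (0.022) and -1.28 ± 0.46 for ASA1 (0.053). It was 2.2 ± 0.49 for JAZ1 (0.0042), 2.87 ± 0.59 for the touch gene TCH2 (0.0028) and 3.57 ± 0.86 for ZAT10 (0.0073). The expansin gene EXPA16 measured -7.05 ± 0.63 (0.00023) and SDG8 -2.47 ± 0.34 (0.00034). Early wound genes had 11 of 21 with a higher response, 11 adjusted over the list alone (median 2.18, or 2.15 at the floor, camera adjusted p 2.11e-05), and JAZ repressors 5 of 13, 7 adjusted over the list alone (1.90, 0.00451), both with adjusted p = 0.99 with an estimated correlation. With both sdg8-2 replicate 2 libraries left out the early wound count was 6 (2.36, 4.89e-05), and the JAZ list had 2 higher and no longer passed camera (1.17, 0.0527). Tryptophan genes had 3 of 13 with a lower response, 6 adjusted over the list alone (-0.87, 0.239). In all, 5423 genes passed the edgeR test, 2439 higher and 2984 lower, 3860 of them by at least 2-fold. With limma on TPM 1252 were higher and 3292 lower. The count was 1297 when only the compared libraries were fitted, where the calls of TSB1 (-1.54) and TSA1 (-1.02) ended. The call of TSA1 also ended with both sdg8-2 replicate 2 libraries left out (-0.91) and without sdg8-2 2 h replicate 2 (-0.79), sdg8-2 time 0 replicate 1 (-0.93), Col-0 2 h replicate 1 (-0.61) or Col-0 time 0 replicates 1 (-1.05) and 2 (-0.99). ASA1 passed with the stricter filter (-1.26), overlapping genes summed (-1.27), limma on TPM (-1.54), DESeq2 (-1.26), both sdg8-2 replicate 2 libraries left out (-1.88) or either of them (-1.63 at 2 h, -1.47 at time 0), and was -0.992 without sdg8-2 2 h replicate 1.

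Set against each other, the coi1-2 response was weaker than the sdg8-2 response for the tryptophan and indole genes. The difference was -2.83 ± 0.33 for IGPS (adjusted p 0.0013), -2.60 ± 0.31 for TSA1 (0.0014), -4.97 ± 0.60 for CYP79B2 (0.0014), -3.37 ± 0.49 for CYP83B1 (0.0066) and -1.18 ± 0.46 for ASA1 (0.13). It was 4.91 ± 0.76 for the nitrate reductase gene NIA1 (0.0089). Tryptophan genes had 8 of 13 lower, 9 and 1 higher adjusted over the list alone (median -1.99, camera adjusted p 3.81e-15; adjusted p = 0.139 with an estimated correlation). JAZ repressors had 0 of 13, 0 adjusted over the list alone (-1.23, 0.0247; adjusted p = 0.966 with an estimated correlation), with 4 lower at an unadjusted p below 0.05 in edgeR and 2 by DESeq2. With both sdg8-2 replicate 2 libraries left out the tryptophan list had 5 lower (-1.46, 8.73e-14) and the JAZ list no longer passed camera (-1.07, 0.0589). In all, 1204 genes passed the edgeR test, 677 higher and 527 lower, 800 of them by at least 2-fold. With both sdg8-2 replicate 2 libraries left out 294 were called, 14.7% of the reported calls among them. The count was 723 with no filter, 496 with limma on TPM (349 higher, 147 lower), 2705 with DESeq2, 1892 with a replicate block in each genotype and 4 when only the compared libraries were fitted. The last setting ended the calls of IGPS (-2.83), TSA1 (-2.61), CYP79B2 (-4.99), CYP83B1 (-3.38) and NIA1 (4.92). The count was 226 and 15 without coi1-2 2 h replicates 1 and 2, the latter ending the calls of CYP83B1 (-3.43) and NIA1 (4.80). It was 21 and 75 without coi1-2 time 0 replicates 1 and 2, the former ending that of NIA1 (5.07). It was 2357 and 415 without sdg8-2 2 h replicates 1 and 2, and 3981 and 439 without sdg8-2 time 0 replicates 1 and 2.

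**Figure D3:**
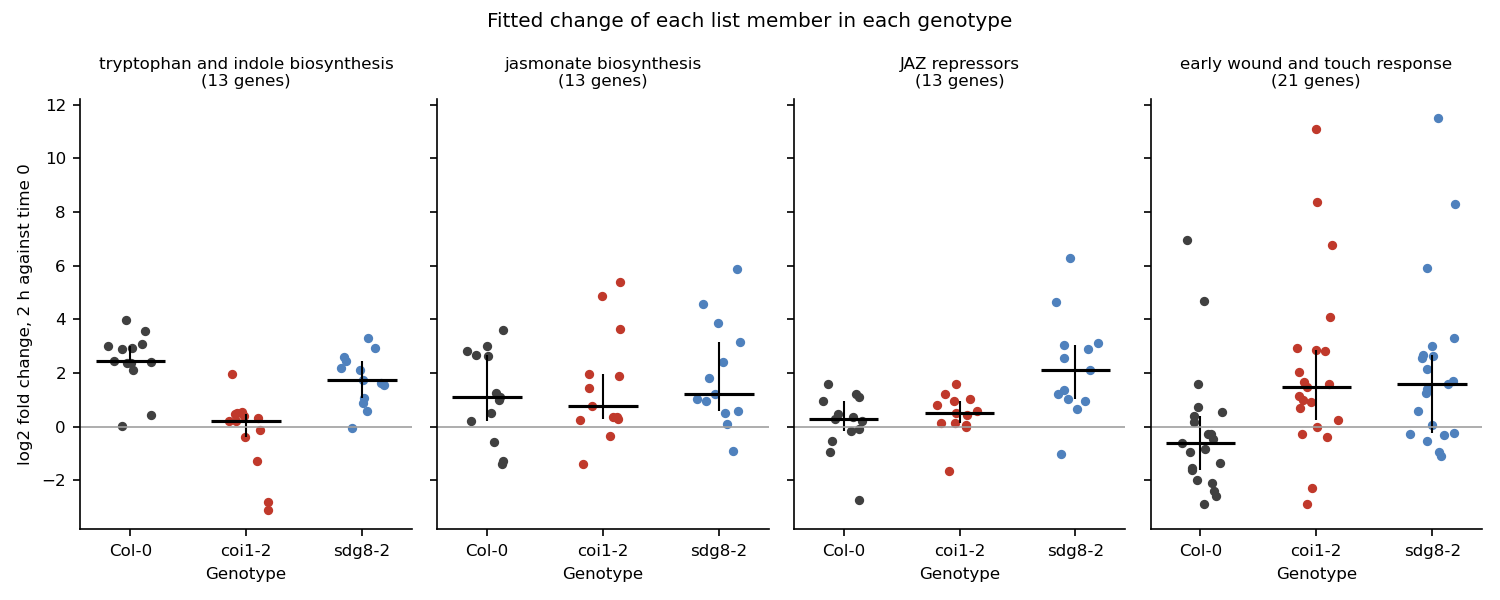
Fitted log2 fold change at 2 h against time 0 (y axis) of each member of 4 lists, 1 point per gene, in Col-0, coi1-2 and sdg8-2 (x axis), with the median as a horizontal line and the quartiles as a vertical line; points of genes at 0 counts in a group depend on the prior count. The tryptophan genes have a median of 2.44 in Col-0 and 1.74 in sdg8-2.

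The induced set of 886 genes, higher in the mean of 1 h and 4 h than at 10 min in Col-0, responded less in coi1-2. It was chosen outside the compared libraries but on Col-0 alone. No set was chosen on a mutant, so a smaller median in another genotype may partly follow from the choice. The median log2 change of the 886 genes at 2 h was 1.99 in Col-0, 0.94 in coi1-2 and 1.62 in sdg8-2, and 8 of them belonged to the jasmonate lists. The median difference was -0.96 in coi1-2 (quartiles -1.90 and -0.17), with 179 genes called weaker and 2 stronger. It was -0.40 in sdg8-2 (quartiles -1.33 and 0.43), with 143 weaker and 36 stronger, against -0.03 over all genes in each. The replicate pairs gave -0.88 and -1.01 in coi1-2 and -0.11 and -0.70 in sdg8-2, a spread wider than the sdg8-2 value. That value moved to -0.04 with both sdg8-2 replicate 2 libraries left out, -0.10 without that of time 0 alone and -0.62 without sdg8-2 2 h replicate 1. The response minus that of Col-0 was called lower in both mutants for 830 genes, of 1211 and 2984, where independent lists would share 171. It was called higher in both for 564 genes, where independent lists would share 102. These counts go by the sign of the difference. Genes that fell further in the mutants therefore count as lower, whichever way they moved in Col-0. Unchanged mutants simulated against the same Col-0 libraries had at most 1 gene called, so their overlap of 0 does not show what shared controls add. Part of the excess may come from the shared controls: across genes the differences correlated at 0.570 against a simulated 0.469, and their covariance was 1.08 against 0.295. The difference of 0.789 holds any shared effect of the mutants together with any shift or variation of the shared Col-0 libraries beyond the simulated spread. The overlap of lower differences was 121 and 239 without coi1-2 2 h replicates 1 and 2, and 300 and 154 without coi1-2 time 0 replicates 1 and 2. It was 260 and 276 without Col-0 2 h replicates 1 and 2, and 400 and 242 without Col-0 time 0 replicates 1 and 2. It was 504 with the 2-fold threshold and 1272 with both sdg8-2 replicate 2 libraries left out.

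Across all comparisons 121 of 400 list tests passed camera at the preset correlation and 13 passed with an estimated correlation. The latter were early wound genes and AP2/ERF factors at 10 min, tryptophan genes at 2 h, anthocyanin and cytokinin genes at 8 h and anthocyanin genes at 12 h in Col-0. In coi1-2 against Col-0 they were glucosinolates at time 0 and tryptophan, jasmonate biosynthesis, catabolism, jasmonate response and glucosinolate genes at 2 h, and the last was the tryptophan list in the coi1-2 response minus the Col-0 response.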

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

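The tests of library composition, of a constant difference between library series and of MYC2 summed with its neighbour were chosen after the result they measure was seen. The other tests in this part were written down first.

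The results below stand out because the response from time 0 to 2 h differed between genotypes in a test of the difference itself. In the coi1-2 response minus the Col-0 response 2097 genes passed. The tryptophan list had a median of -2.46, with ASA1 at -2.46, TSA1 at -3.63, IGPS at -3.08, CYP79B2 at -5.87 and CYP83B1 at -4.14. The early wound list stood at 1.89 and the AP2/ERF list at 1.52, neither past the threshold with an estimated correlation (adjusted p = 0.471 for each), with ZAT10 at 4.80 and ERF1A at 3.99, and MIOX2 at -7.64. In the sdg8-2 response minus the Col-0 response 5423 genes passed, with the early wound list at 2.18 and the JAZ list at 1.90. Both lost their call with an estimated correlation (adjusted p = 0.99), and the JAZ list also with both sdg8-2 replicate 2 libraries left out (1.17, 0.0527). Genes with a different response in sdg8-2 were TSB1 at -1.55, TSA1 at -1.03, JAZ1 at 2.2, TCH2 at 2.87, ZAT10 at 3.57, EXPA16 at -7.05 and SDG8 at -2.47. In the coi1-2 response minus the sdg8-2 response 1204 genes passed, with the tryptophan list at -1.99 and the JAZ list at -1.23. Both lost their call with an estimated correlation (adjusted p = 0.139 and 0.966), and the JAZ list also with both sdg8-2 replicate 2 libraries left out (-1.07, 0.0589). Genes that differed between the mutants were IGPS at -2.83, TSA1 at -2.60, CYP79B2 at -4.97, CYP83B1 at -3.37 and NIA1 at 4.91.

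The sdg8-2 replicates differed in light-harvesting and clock genes, with LHCB1.1 at 59.9 and 9948 TPM and CCA1 at 0.2 and 45.7 TPM in replicates 1 and 2 at time 0. A library composition set by a few abundant genes is argued against by the clock list. Its median absolute log2 difference between the sdg8-2 replicates was still 4.33 at time 0 and 3.18 at 2 h after TMM scaling. In the 10 groups of Col-0 and coi1-2 it was at most 0.657. Replicate 2 being Col-0 is argued against by 37 genes chosen as low in replicate 1 alone. They had a median of -3.40 against Col-0 in replicate 2 and -3.80 in replicate 1. These genes were not compared with coi1-2, so they do not speak to that genotype. SDG8, whose level is uncertain, was at most 2.86 TPM in sdg8-2 replicate 2 and at least 5.31 TPM in Col-0. A candidate explanation is leaves collected at another phase of the daily clock, since 7 of 8 clock-output genes outside the lists differed at time 0 in the direction of an earlier phase, and 8 at 2 h. The labels give no time of day, so this stays a hypothesis, and no biological explanation was tested because both libraries share a group.

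Early wound and touch genes were lower in both mutants than in Col-0 at time 0, with medians of -2.57 in coi1-2 and -2.17 in sdg8-2. A constant difference between the library series of the mutants and of Col-0 would cancel in the responses, but 5 of the 21 members had a higher response called in coi1-2 and 11 in sdg8-2, and none a lower one. Col-0 time 0 leaves already in the early response cannot be told apart from a genotype effect: 665 other early genes, chosen without time 0, stood 1.5 higher at Col-0 time 0 than at 4 h, and measured -1.13 in coi1-2 and -0.98 in sdg8-2 against Col-0 at time 0, where the latter just missed the bound of -1 set in advance. At 2 h the same set measured -0.02 and 0.05. An effect of either mutation at time 0 and any handling that differed between the series stay open, and neither was tested.

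MYC2 had 0 counts in all 4 coi1-2 libraries, while the overlapping gene AT1G32630 held reads there. The count of 0 was not particular to coi1-2. In sdg8-2 at time 0, MYC2 had 0 counts in replicate 1 and 846 in replicate 2, where AT1G32630 held 628 and 919. Reads of MYC2 given to that gene are argued against as the whole cause, since the sum of both still measured -3.69 ± 0.59 at 2 h (adjusted p 0.00115) and -4.29 at time 0 in coi1-2 against Col-0. By the same edgeR test the sum was also lower in sdg8-2 than in Col-0. It measured -1.94 ± 0.55 at time 0 (adjusted p 0.0241) and -1.65 ± 0.54 at 2 h (0.0266). How far the split between MYC2 and AT1G32630 shaped the counts of 0 stays open. An effect of either mutation on MYC2 was not tested apart from the library series.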

How the results depend on the processing

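Leaving out both sdg8-2 replicate 2 libraries, summing overlapping genes and the replicate block within each genotype were chosen after seeing the data, and the other alternatives were planned. With RLE size factors, the stricter filter, effective length offsets, organelle genes left out or overlapping genes summed, every count that was run was within 1.5 times the reported one. The induced-set medians were run with all of these but organelle genes left out, and moved by less than the replicate spread. The replicate numbers were not shown to pair the samples (of 66 pairs of groups 15 had correlated replicate differences above 0.1 and 1 below -0.1), and with the replicate as a block no count moved by more than 1.5 times. Replicate differences went together for part of the groups within a genotype, in 13 of 28 pairs of Col-0 times above 0.1 (at most 0.380, 4 h with 8 h) and between sdg8-2 time 0 and 2 h (0.345), but not between coi1-2 time 0 and 2 h (0.042). With a separate replicate block within each genotype 10941 genes were called within sdg8-2 and 6546 for its response minus that of Col-0, the coi1-2 response rose to 3243 and coi1-2 minus sdg8-2 to 1892, and no other count moved by more than 1.5 times. Neither block moved a call of a named gene.

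The share of higher calls moved by more than 10 points with limma on TPM, to 1706 higher and 2416 lower at 30 min, 3337 and 4157 at 1 h, 1842 and 550 at 4 h, 1733 and 549 at 8 h, 2564 and 730 at 12 h. For sdg8-2 against Col-0 it gave 877 and 2070 at time 0 and 1211 and 6000 at 2 h, for the sdg8-2 response minus that of Col-0 1252 and 3292, and for coi1-2 minus sdg8-2 349 and 147. This setting left out the TMM factors. These were 0.87 to 0.94 in the Col-0 libraries of 30 min and 1 h, and 1.09 to 1.12 at 4 h, 8 h and 12 h. At Col-0 time 0 they were 1.03 and 1.00. Both sdg8-2 replicate 2 libraries had 0.83, against 1.02 and 1.04 in replicate 1 at time 0 and 2 h. How far the scaling accounts for the shifts was not tested.

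A threshold of 2-fold by construction calls fewer genes: 2955 at 30 min, 5386 at 1 h, 2428 at 2 h, 1594 at 8 h, 2005 at 12 h, 7000 for any change, 1674 and 1419 for coi1-2 against Col-0 at time 0 and 2 h, 2082 and 3690 for sdg8-2, 2672 within coi1-2, 6413 within sdg8-2, 800 for coi1-2 minus sdg8-2 and 504 for the overlap. Fitting only the libraries compared, which takes the spread from these alone, gave 289 at 10 min, 821 at 30 min, 5652 and 7823 for coi1-2 against Col-0 at time 0 and 2 h, 1 and 2796 for sdg8-2, 11965 within coi1-2, 904 within sdg8-2, 6761 and 1297 for the coi1-2 and sdg8-2 responses minus that of Col-0, and 4 for coi1-2 minus sdg8-2. DESeq2 gave 884 at 10 min, 3176 at 4 h, 3555 for the coi1-2 response and 2705 for coi1-2 minus sdg8-2. That last comparison gave 723 with no filter and 496 with limma on TPM, which also moved the induced-set median in coi1-2 to -0.86; the cause was not tested.

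With both sdg8-2 replicate 2 libraries left out, counts were 6400 at 2 h, 3994 at 4 h, 5110 at 8 h and 5653 at 12 h, 5146 and 4916 for coi1-2 against Col-0 at time 0 and 2 h, 4333 for the coi1-2 response, 294 for coi1-2 minus sdg8-2 and 1272 for the overlap. Comparisons of Col-0 and coi1-2 kept 97.2% to 100% of their reported calls, those with sdg8-2 against Col-0 56.4% at time 0 and 69.3% at 2 h. LHCB1.1 in sdg8-2 at 2 h reversed, to -0.088 there and to -0.093 without sdg8-2 2 h replicate 2, and was 7.79 without sdg8-2 2 h replicate 1. Comparisons of Col-0 and coi1-2 contrast no sdg8-2 library, so their shifts came through the shared fit, by its spread, filter or scaling. Which of these acted was not tested, nor was the cause of the other shifts.

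Where 1 library is left out its group has 1 sample, which is assumed to vary like the other groups. Counts then ran from 119 to 642 at 10 min, 2388 to 5929 at 30 min, 5511 to 6623 at 1 h, 1614 to 2748 at 2 h, 462 to 1565 at 4 h, 382 to 2174 at 8 h and 651 to 2665 at 12 h. For coi1-2 against Col-0 they ran from 424 to 1260 at time 0 and 512 to 1131 at 2 h, and for sdg8-2 from 1335 to 5916 and 4529 to 7789. They ran from 1735 to 2716 within coi1-2, 9026 to 9688 within sdg8-2, 305 to 1012 and 3703 to 6266 for the coi1-2 and sdg8-2 responses, 15 to 3981 for coi1-2 minus sdg8-2, 9070 to 12174 for any change and 121 to 1068 for the overlap. Induced-set medians ran from -1.12 to -0.76 in coi1-2 and -0.62 to -0.10 in sdg8-2.

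Of 400 list tests 121 passed as reported and 13 with an estimated correlation, which widens the test by construction; 126 passed with fry, 123 with the block, 124 with RLE, 136 with both sdg8-2 replicate 2 libraries left out and 132 with the block within each genotype. Of the 121 these kept 90, 119, 120, 114 and 119 in the same order, and none that passed in both turned direction. For the 157 named gene results, 2601 values under alternatives gave the reported direction and side of the threshold in 2506, a lost call in 77, a gained call in 16 and a reversal in 2. Lost calls numbered 47 with 1 library left out and 25 when only the compared libraries were fitted. A named gene had no value where it did not pass that setting's own filter, in 1 case each for the stricter filter, the compared libraries alone and limma on TPM. These totals favour stable genes, since fragile ones were mostly left unnamed.

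Of 120 list and comparison pairs with a member at 0 counts in a compared group, 63 had a median that moved when such members were set to 3 counts per library, by at most 2.71. With 30.1 M counts in the shallowest library, genes such as WOX11, at most 0.22 TPM, lie near the limit of detection, and their absence at earlier times was not shown.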

Other observations

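The genes ERF114 and RNS1 were higher at 2 h than at time 0 in both coi1-2 and Col-0, and THI2.1 and TH8 had low means in coi1-2 at 2 h. No test of a difference between genotypes is given for these genes. The wound factor gene ERF114 was at 0 TPM in both Col-0 libraries at time 0 and reached 12.12 and 11.01 TPM at 2 h, 14.99 and 14.66 TPM in coi1-2 and 17.38 and 13.60 TPM in sdg8-2. The wound-induced ribonuclease gene RNS1 had a mean of 75.04 TPM in Col-0, 58.9 TPM in coi1-2 and 156.7 TPM in sdg8-2 at 2 h, against 0.025 TPM in Col-0 at time 0. Within coi1-2, from means of 0.015 and 0 TPM at time 0, the edgeR adjusted p was 3.5e-07 for ERF114 and 6.7e-05 for RNS1. The thionin gene THI2.1, which jasmonate induces, had means of 67.1, 0.18 and 20.6 TPM in the same order, and the thioredoxin gene TH8 5.21, 0.35 and 5.46 TPM.

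The defensin gene PDF1.2A, at 0 TPM in both Col-0 libraries at time 0, stood at 2.92 and 4.71 TPM at 8 h and 103.09 and 55.59 TPM at 12 h. The lipid-transfer protein genes AT4G12490 and AT4G12500 had means of 4.40 and 5.84 TPM at 4 h and 172.8 and 96.7 TPM at 12 h. AZI1, which lies beside them and was chosen after its values were seen, had 7.15 and 95.2 TPM. The difference between 4 h and 12 h was not tested.

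BHLH100 and bHLH38, 2 related genes also chosen after their values were seen, were at 0 TPM in sdg8-2 at 2 h. BHLH100 had means of 46.5 TPM in Col-0, 1.79 TPM in coi1-2 and 17.45 TPM in sdg8-2 at time 0, and 23.3, 0.075 and 0 TPM at 2 h. The gene bHLH38, which shares reads in 20 libraries, had 18.0, 1.55 and 7.41 TPM at time 0 and 28.9, 0.02 and 0 TPM at 2 h.

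The chaperone gene HSP101 measured 236.67 and 3.56 TPM in the replicates of Col-0 at 30 min and 79.97 and 18.94 TPM at 1 h, against 6.33 and 4.63 TPM at time 0. ERF109 measured 59.53 and 293.64 TPM in the same 30 min libraries, and 17.9% of genes differed at least 2-fold between them.

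The test in this paragraph was written down before its result was seen. Morning clock genes were near 0 throughout Col-0, with CCA1 at most 0.45 TPM, LHY at most 0.78 TPM and PRR9 at most 0.18 TPM in the 16 libraries, from time 0 to 12 h. A possible explanation is Col-0 libraries collected at 1 phase of the daily clock, in which case at least 7 of 8 clock-output genes were to change less than 2-fold at 12 h. Only 4 did, but none of the other 4 (CDF3, COL1, RVE7 and FKF1) passed the test, so sampling at 1 phase cannot be told apart from a change in phase over 12 h. Their failure to pass says little of Col-0, since the fit takes 1 spread per gene from all libraries. Between the sdg8-2 replicates they differed by log2 5.79, 3.93, 4.40 and -1.16 at time 0 (FKF1 by -8.51 at 2 h). With both sdg8-2 replicate 2 libraries left out, the clock list at 12 h had 1 of 16 genes called higher and 3 lower.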
